A study of Arabidopsis thaliana with 4 samples.

How the data were processed

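The samples are 4 libraries of polyadenylated RNA from single plants of Arabidopsis thaliana, 2 of wild type and 2 that overexpress PPD3, grouped by the genotype given in the labels. Per the labels' protocols, total RNA was extracted with a plant RNA kit that includes a DNA removal step, libraries were made with a TruSeq RNA kit, which does not mark the strand, and sequenced as 150-bp single reads on an Illumina instrument. The deposited values are whole-number counts of reads per gene, 1 file per library, with no normalization. The genome build TAIR10 and the tool DESeq2 are named in the submitters' processing notes, with no version of the tool. The aligner, the counting tool and the annotation are not given in the sources used here. The 5 rows at the end of each file that name no gene carry the names that HTSeq-count uses, such as reads without a feature, ambiguous reads and reads whose alignment was not unique. Such counting leaves reads with several alignments out of genes, which lowers the counts of near-identical gene copies, and it leaves out reads over overlapping genes.

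Each file holds 33977 gene rows, of which 25188 had a count in at least 1 library. The rows that name no gene stayed out of library sizes and tests. As shares of all counted reads, reads without a feature were 0.845%, 0.941%, 0.840% and 0.713%, and ambiguous reads 4.07%, 4.18%, 3.78% and 3.67%, in wild-type plants 1 and 2 and overexpressor plants 1 and 2. Reads with several alignments were 4.60%, 4.18%, 5.16% and 5.61% in that order. The 10 most abundant genes held 5.26% to 5.64% of gene counts per library. With 33771093 to 40727172 gene counts per library, counting error is small for most genes named, and the spread between plants sets the precision. With 2 plants per genotype the fit has 2 residual degrees of freedom, to which edgeR's moderation added a prior of 2.36.

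Gene names and products came from a RefSeq annotation of TAIR10.1, matched by locus identifier: 32548 of 33977 rows matched, and 10804 had a symbol other than the locus. Coordinates are given for PPD3 alone and are those of TAIR10.1. Of the genes the naming rule selects, 7 of 34 overlap another annotated gene. Where the reference symbol differs from a common one, both are given for some genes.

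Counts were tested with edgeR 4.0.16 in R 4.3.3, with its filter at default settings (a minimum count of 10 and a minimum total of 15), TMM scaling, a quasi-likelihood F test of genotype with no covariate, and Benjamini-Hochberg adjustment over the 19919 genes kept. An adjusted p under 0.05 was called, with no minimum fold. The SE of a log2 fold change is its size divided by the square root of the F statistic. DESeq2 1.42.0 (Wald test, its own size factors and independent filtering) was the other count test, and the 4794 genes for which it gave no adjusted p stayed uncounted. CPM values are TMM-scaled. TMM factors ran from 0.984 to 1.03.

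The study's labels give no gene lists. A set of 27 lists of nuclear genes (482 memberships) and 2 lists of organelle-encoded genes was written from general knowledge before the data were examined, with the tests, the alternatives and the naming rule. Each list with at least 5 tested members was compared with all other genes by camera (limma 3.58.1, on voom log2 CPM, two-sided, preset correlation of 0.01, adjusted over lists), with an estimated correlation and fry beside it. The run with an estimated correlation tests on the fit's 2 residual degrees of freedom, while the preset one takes them from the number of genes. With so few plants the former has little power. One departure from the plan was made: the rule for members whose symbol the reference gives to another locus would have replaced 3 loci by genes of other proteins, so the written loci were kept and the rule was run as an added alternative. The planned identity of PPD3 depended on the reference naming it, which it does not, and AT1G76450 was kept.

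The naming rule takes PPD3, then up to 12 called genes in each direction by fold change, with groups that do not overlap and a mean log2 CPM of at least 1. Those genes must carry a symbol. It adds from each list up to 2 called members per direction, or the member with the smallest p where none was called, and, if under 5 genes are called in all, the 5 with the smallest p in each direction. Other genes named were chosen after their values were seen.

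Alternatives set in advance were other scalings (DESeq2 size factors, library size, upper quartile), DESeq2, no filter, a filter of at least 5 CPM in 2 libraries, organelle genes left out, the replicate number as a block, each plant left out in turn, a 2-fold minimum, an adjusted p of 0.10, and for lists the estimated correlation and fry. Added after the data were seen were a crossed replicate block, limma with voom weights, edgeR with robust moderation, 523 genes left out (jasmonate and touch members and genes over 4-fold apart between plants of 1 genotype), the symbol rule, PPD3 left out of the PsbP list, and DESeq2 with plants left out or with blocks.

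The gene tests were run on simulated counts for the 19919 genes and 2 against 2 plants, with 200 genes changed by known folds. A further list of genes, raised by less, was not counted among the false calls. With an equal spread for genes of like abundance, edgeR recovered 37.0% of genes changed by a log2 of 1 and 100% of those changed by 3, with 3 false calls, and DESeq2 recovered 42.0% and 99.0% with 11 false calls. With spreads as unequal between genes as in these plants, edgeR recovered 0% and 57.0% with 6 false calls, and DESeq2 recovered 51.0% and 95.0% with 211 false calls. Python 3.11.15 read the files and drew the plots.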

Results

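Messenger RNA was sequenced from single plants of Arabidopsis thaliana, 2 of the Col-0 accession, the common laboratory wild type, and 2 of the same background that overexpressed PPD3. PPD3 belongs to the PsbP-domain family, proteins related to an extrinsic subunit of photosystem II. The labels number the plants of each genotype as biological replicates 1 and 2. They were grown on soil at 22 °C with 16 h of light and frozen at bolting, when the flowering stem emerges. One label speaks of entire plants and another of the rosette, so the share of stem and bud tissue in the samples is not settled. Counts assigned to genes summed to 36990201 and 33771093 in wild-type plants 1 and 2, and to 40727172 and 34793720 in overexpressor plants 1 and 2. The design holds 1 comparison, overexpressor against wild type, which asks which transcripts differ when PPD3 is overexpressed. Values below are CPM (counts scaled to a fixed library total) after TMM scaling, given as mean ± SD over 2 plants, and log2 fold changes are overexpressor over wild type with their SE.

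The overexpressed transcript was measured first. The locus taken as PPD3 is AT1G76450, annotated as a photosystem II reaction center PsbP family protein, on the plus strand of chromosome 1 from 28684551 to 28686244 in TAIR10.1, with 10 exons. The reference table used here does not attach the symbol PPD3 to that locus, so the identity rests on the name PsbP-domain protein 3 in general knowledge. Its raw counts were 3800 and 2460 in wild-type plants 1 and 2, and 113628 and 111903 in overexpressor plants 1 and 2. In scaled units the level was 86.7 ± 22.7 CPM in wild type and 3050 ± 303 CPM in the overexpressor, a 35.2-fold difference (log2 fold change 5.14 ± 0.31). Both overexpressor plants lay far above both wild-type plants. Even so, edgeR's adjusted p was 0.0623, short of the 0.05 threshold, and DESeq2's was 4.42e-86. The neighbouring gene AT1G76460 overlaps the locus in the annotation. With reads that carry no strand, its lower level (35.8 ± 4.6 CPM in wild type and 21.2 ± 1.1 in the overexpressor) is uncertain. Among the 11 tested members of the PsbP-domain family, 10 had positive fold changes, with a median log2 fold change of 0.41. The wild-type plants differed by more in this list, plant 1 over plant 2 by a median log2 difference of 0.61, and the overexpressor plants by -0.09. PPD3 was the only member to pass upward, and PSBP-2 the only one downward (-0.85 ± 0.18), when p-values were adjusted over the list alone in edgeR. As a set the list passed only with PPD3 in it (camera adjusted p = 0.0146, and adjusted p = 0.690 with an estimated correlation). The 10 other members did not pass (9 with positive fold changes, camera adjusted p = 0.0534, and adjusted p = 0.753 with an estimated correlation).

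**Figure D1:**
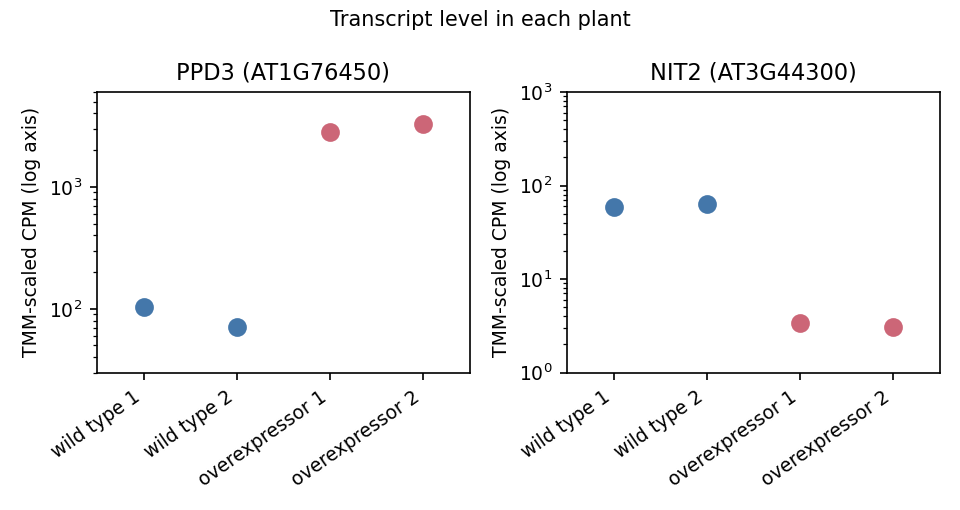
Transcript level of PPD3 (left) and NIT2 (right) in each of the 4 plants, as TMM-scaled CPM on a log axis, with 1 point per plant and genotype by colour (blue for wild type, red for overexpressor). PPD3 was at 103 and 70.7 CPM in wild type and at 2836 and 3264 CPM in the overexpressor, and NIT2 at 58.6 and 62.8 CPM against 3.34 and 3.06 CPM.

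Across all transcripts, the gene lists that stood lowest in the overexpressor plants by set test were senescence (median log2 fold change -2.77), cold, drought and abscisic acid (ABA) response (-0.98), auxin response (-0.82) and clock genes (-0.55). Flavonoid (1.09), dividing-cell (0.92) and glucosinolate (0.72) genes stood higher by the same test. All these calls were made with camera's preset correlation of 0.01 between genes. None held with an estimated correlation (camera adjusted p = 0.531 for each but the floral list, at 0.652). That run tests on the fit's 2 residual degrees of freedom, while the preset one takes them from the number of genes. It thus had little power, and a call lost there is not shown to be undone by correlation between genes. For the clock list the estimated correlation, -0.0065, lay below the preset one, yet camera's unadjusted p went from 1.88e-05 to 0.0423. Correlation between genes does not account for that loss, and the drop in degrees of freedom acts on every list. Of 19919 genes tested, 1 passed edgeR's adjusted p of 0.05, and it was lower: NIT2 (AT3G44300), a nitrilase of the family that can turn indole-3-acetonitrile into auxin. NIT2 stood at 60.7 ± 2.9 CPM in wild type and 3.2 ± 0.2 in the overexpressor, 18.9-fold lower (log2 fold change -4.24 ± 0.12, edgeR adjusted p = 0.0363). Its tandem copies NIT1 (854 and 993 CPM, wild type and overexpressor) and NIT3 (5.64 and 7.57 CPM) did not pass in either tool. Counting of this kind leaves reads that match several such copies out of the gene counts, so the levels of these copies are uncertain. No gene passed upward in edgeR, where 6587 genes had an unadjusted p under 0.05 against 996 by chance. DESeq2 called 1703 genes higher and 1969 lower at the same threshold. In simulated counts with spreads as unequal between genes as in these plants, it made 211 false calls. It recovered 51 and 95 of 100 genes changed by a log2 of 1 and 3. Far fewer genes were changed there than DESeq2 called here, genes varied independently, and both genotypes had the same spread. The simulation thus does not give the share of false calls among the DESeq2 calls here. At an adjusted p of 0.10, edgeR called 1904 higher and 2225 lower, and 3324 genes were in both that set and the DESeq2 calls. In 67.0% of tested genes the 2 genotypes did not overlap, against 33.3% by chance. The single edgeR call was lost when any 1 plant was left out, while NIT2's log2 fold change then ran from -4.32 to -4.18. Such fits keep 1 plant in 1 genotype and fewer residual degrees of freedom, so the loss alone does not tell whether the call is stable. DESeq2's 3672 calls became 510 without wild-type plant 2, 962 without overexpressor plant 2, 1740 without overexpressor plant 1 and 4505 without wild-type plant 1.

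Besides PPD3 and NIT2, the naming rule takes the genes with the smallest unadjusted p in each direction, which did not pass edgeR's threshold. The higher ones were AT3G04650, an FAD/NAD(P)-binding oxidoreductase (5.62-fold), BAM5, a beta-amylase (21.6 ± 1.9 CPM in wild type and 78.5 ± 2.7 in the overexpressor), AT4G22517, a lipid-transfer-like protein (log2 fold change 2.07 ± 0.16), and LHCB4.3, a minor antenna protein of photosystem II (33.9 ± 4.9 and 117 ± 0.9 CPM). On the lower side, besides NIT2, were UBC7, a ubiquitin-conjugating enzyme (18.6 ± 2.0 and 0.331 ± 0.097 CPM), and AACT1 (AT5G61160), annotated as an anthocyanin acyltransferase (22.1 ± 2.4 and 1.33 ± 0.20 CPM). With them were NAC047, a transcription factor of the NAC family (8.19 ± 0.52 and 0.739 ± 0.014 CPM), and BHLH101, a regulator of iron uptake (log2 fold change -2.58 ± 0.12). Each of these 8 genes had an edgeR adjusted p of 0.0623, a value that the adjustment gave to 681 genes. DESeq2's adjusted p ran from 1.57e-46 for UBC7 to 1.09e-11 for AT4G22517. BHLH101 overlaps an abundant gene, AT5G04140, in the annotation, so its count is uncertain without strand, and AT4G22517 overlaps another gene as well.

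**Figure D2:**
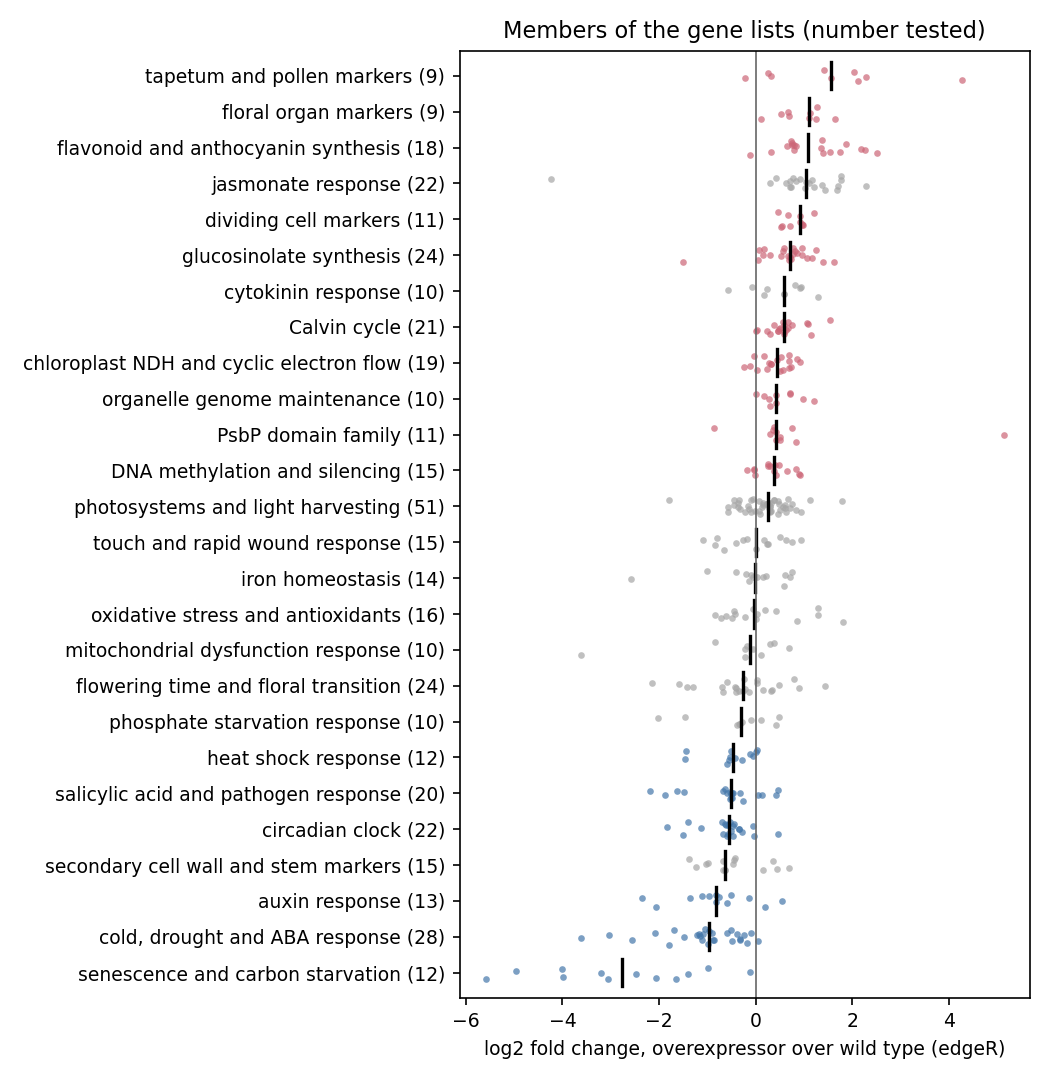
Log2 fold change of each tested member of the 26 gene lists with a set test, overexpressor over wild type (x axis), with lists on the y axis, 1 point per gene and a black bar at the list's median. Coloured lists passed the set test with the preset correlation (red for higher, blue for lower) and grey ones did not. Medians run from -2.77 for the senescence list to 1.56 for the tapetum and pollen list.

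Gene lists fixed before the data were examined describe these differences by process. In each list, members are said to have risen or fallen when they passed edgeR with p-values adjusted over the list alone. Over all genes tested, 0 list members passed at 0.05 in edgeR, where the 1 call, NIT2, is in no list. Examples other than the member with the smallest p in each list were chosen after their values were seen. Of 26 lists tested as sets against all other genes with camera, 10 were higher and 6 lower at an adjusted p of 0.05 with the preset correlation, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.531 and 1 list had an unadjusted p under 0.05. The run with an estimated correlation had 2 residual degrees of freedom and so little power to pass any list. The self-contained test fry (limma) called 0 lists, with a lowest adjusted p of 0.0546 and 9 lists at an unadjusted p under 0.05. Under 3 other scalings each list median kept its sign, apart from the small medians of the antioxidant, touch and iron lists.

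Senescence and carbon starvation genes showed the lowest list median. All 12 tested members were lower in both overexpressor plants than in both wild-type plants, and 10 fell, with a median log2 fold change of -2.77 (camera adjusted p = 3.50e-06, and adjusted p = 0.531 with an estimated correlation). DESeq2 called the same number, 10. SAG13, a marker of leaf senescence, went from 65.4 ± 18.4 CPM to 7.87 ± 1.23 (log2 fold change -3.05 ± 0.26). The NAC regulators of senescence NAC6, also called ORE1 (-3.98 ± 0.43), and NAP (-4.96 ± 0.64) fell, as did the dark-inducible SEN1 (AT4G35770, -5.59 ± 0.75) and the asparagine synthetase ASN1 (-4.01 ± 0.87). ACD1, which breaks down chlorophyll's ring, was at -0.11 ± 0.12 and did not pass, and DIN2 (-2.49 ± 1.33) did not pass either. In wild type, SEN1 differed between the plants (68.7 and 224 CPM), and ASN1 did as well (37.4 and 128 CPM), against 3.69 and 2.36 CPM and 7.59 and 2.63 CPM in the overexpressor.

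Cold, drought and ABA response genes were lower as well. Of 28 tested members 27 had negative fold changes and 15 fell, with a median of -0.98 (camera adjusted p = 1.32e-06, and adjusted p = 0.531 with an estimated correlation), and DESeq2 called 17 lower. GolS2, which makes galactinol for raffinose sugars, went from 29.4 ± 3.9 CPM to 2.42 ± 0.67 (12.2-fold lower). The ABA-induced phosphatase HAI1 (-3.03 ± 0.32), the transcription factor ABF3 (-1.69 ± 0.20), the dehydrin RAB18 (AT5G66400, -1.80 ± 0.34) and LTI78, also called RD29A (-1.17 ± 0.20), all fell. Members that did not pass include NCED3, the key enzyme of ABA synthesis (-0.10 ± 1.26), and RD26 (-0.60 ± 1.4). In overexpressor plants 1 and 2, NCED3 was at 53.8 and 3.59 CPM and RD26 at 142 and 5.22 CPM. In wild-type plants 1 and 2, NCED3 was at 16.4 and 45.3 CPM and RD26 at 82.4 and 141 CPM.

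Auxin response genes were lower in 11 of 13 tested members, with 6 falling and a median of -0.82 (camera adjusted p = 0.0010, and adjusted p = 0.531 with an estimated correlation). IAA1, an early auxin-induced repressor, was at 21.4 ± 0.1 CPM in wild type and 9.92 ± 0.34 in the overexpressor (2.16-fold lower). IAA2 (-1.36 ± 0.20) and the auxin-conjugating enzyme WES1, also called GH3.5 (-2.36 ± 0.32), fell too. Circadian clock genes were lower in 21 of 22 tested members and 6 fell, with a median of -0.55 (camera adjusted p = 8.17e-05, and adjusted p = 0.531 with an estimated correlation). COR28, a regulator of the clock and of cold response, went from 82.5 ± 0.6 CPM to 31.1 ± 1.4 (2.66-fold lower), and the pseudo-response regulator PRR7 (-1.13 ± 0.21) and RVE1 (-1.84 ± 0.27) fell. LHY, a morning repressor of the clock, was the member with a positive value (0.45 ± 0.16), which did not pass. The time of day of harvest is not given in the sources used here.

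Salicylic acid and pathogen response genes had negative fold changes in 16 of 20 tested members, with a median of -0.51 (camera adjusted p = 0.0043, and adjusted p = 0.531 with an estimated correlation). PR1, the standard marker of salicylic acid signalling, was the 1 member to fall, from 225 ± 49 CPM to 49.4 ± 13.4 (4.55-fold). PR5 (-0.68 ± 0.18) and PAD3, the last enzyme of camalexin synthesis (-1.63 ± 0.44), did not pass in edgeR, and DESeq2 called 5 members lower. Heat shock genes were lower in 10 of 12 members with a median of -0.47 (camera adjusted p = 0.0485, and adjusted p = 0.652 with an estimated correlation), and HSP70 (AT3G12580) fell (-1.44 ± 0.25). The heat shock call was lost without wild-type plant 1 (camera adjusted p = 0.196) or overexpressor plant 1 (camera adjusted p = 0.0869), with a filter of 5 CPM (camera adjusted p = 0.0516), and with PPD3 left out of the PsbP list, which moves the adjustment over lists (camera adjusted p = 0.0517).

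Flavonoid and anthocyanin synthesis genes were higher in 17 of 18 tested members, and in those 17 both overexpressor plants lay above both wild-type plants. 11 rose, with a median log2 fold change of 1.09 (camera adjusted p = 1.32e-06, and adjusted p = 0.531 with an estimated correlation). 4CL3, a ligase that supplies the flavonoid branch, went from 6.67 ± 2.0 CPM to 37.9 ± 2.4 (5.67-fold higher). Wild-type plant 1 was above plant 2 in this list by a median log2 difference of 0.61. Chalcone synthase TT4 (1.75 ± 0.23), flavonol synthase FLS1 (2.27 ± 0.34) and MYB111, a regulator of flavonol genes (2.17 ± 0.30), rose. Not all anthocyanin genes passed. The glycosyltransferase UF3GT (1.39 ± 0.36) and the regulator PAP1 (1.35 ± 0.38) rose, while DFR (0.76 ± 0.35), LDOX (0.79 ± 0.36) and TT8, a regulator of anthocyanin and tannin genes (-0.12 ± 0.30), did not pass.

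Glucosinolate synthesis genes were higher in 23 of 24 tested members, 13 rose and 1 fell, with a median of 0.72 (camera adjusted p = 9.72e-06, and adjusted p = 0.531 with an estimated correlation). SOT17, a sulfotransferase of the last step, went from 34.9 ± 4.2 CPM to 72.7 ± 8.2 (2.09-fold higher). The cytochrome P450 CYP79F2 (1.24 ± 0.20) and the regulator MYB34 (1.63 ± 0.32) rose. MYB51, another regulator of the indole branch, was the member that fell (-1.52 ± 0.44).

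Dividing-cell markers were higher in both overexpressor plants than in both wild-type plants for all 11 tested members, and 10 rose, with a median of 0.92 (camera adjusted p = 3.50e-06, and adjusted p = 0.531 with an estimated correlation). CYCB1;1, a mitotic cyclin, went from 4.18 ± 0.02 CPM to 9.59 ± 0.03 (2.29-fold higher), and SYP111, the cell-plate syntaxin also called KNOLLE, rose by 0.92 ± 0.16 on the log2 scale. Summed over the list, these markers were at 134 and 110 CPM in wild-type plants and at 220 and 211 CPM in overexpressor plants. DNA methylation and silencing genes were higher in 11 of 15 tested members, with a median of 0.38 (camera adjusted p = 0.0024, and adjusted p = 0.531 with an estimated correlation), and 4 rose. These were the CG methyltransferase MET1 (50.1 ± 0.5 CPM in wild type and 93.8 ± 3.8 in the overexpressor), CMT3 (0.92 ± 0.14), the chromatin remodeller CHR1, also called DDM1 (0.84 ± 0.12), and AGO4 (0.65 ± 0.10). DRM2, the methyltransferase of the RNA-directed pathway, was at -0.18 ± 0.12 and did not pass. The dividing-cell markers, higher in the same plants, stand beside these values.

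Photosynthesis lists had positive median fold changes and differed between the wild-type plants. Calvin cycle genes had positive fold changes in all 21 tested members, with a median of 0.58 (camera adjusted p = 2.80e-04, and adjusted p = 0.710 with an estimated correlation), while 0 members passed over the list alone in edgeR, 5 had an unadjusted p under 0.05 and DESeq2 called 5. RBCS2B, 1 of the near-identical small subunits of Rubisco, was at 942 ± 368 CPM in wild type and 2729 ± 330 in the overexpressor (edgeR adjusted p = 0.0775), and its count is uncertain because the copies share reads. Genes of the chloroplast NDH complex and cyclic electron flow had a median of 0.43 over 19 members (camera adjusted p = 0.0241, and adjusted p = 0.753 with an estimated correlation). In edgeR 0 of them passed, 2 had an unadjusted p under 0.05 and DESeq2 called 2. Pnsl5, a subunit of that complex, was at 77.5 ± 13.8 CPM in wild type and 125 ± 9 in the overexpressor. The NDH call was lost without wild-type plant 2 (camera adjusted p = 0.345) or overexpressor plant 1 (camera adjusted p = 0.0671). Photosystem and light-harvesting genes did not pass as a list (51 members, median 0.25, camera adjusted p = 0.0582). In it LHCB4.3 rose (1.78 ± 0.15) and LHB1B1 fell (-1.79 ± 0.20), the latter 1 of several near-identical antenna genes and so uncertain. The photosystem list passed without wild-type plant 1 (camera adjusted p = 8.65e-05), with library size alone as scaling (0.0439) and without a filter (0.0383). Wild-type plant 1 was above wild-type plant 2 by a median log2 difference of 0.33 in the photosystem list, 0.77 in the NDH list and 0.65 in the Calvin cycle list, and the overexpressor plants differed by -0.13, -0.03 and -0.12.

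Organelle genome maintenance genes had positive fold changes in all 10 tested members, with a median of 0.42 (camera adjusted p = 0.0024, and adjusted p = 0.652 with an estimated correlation). The single-stranded DNA-binding proteins WHY3 (13.5 ± 1.7 CPM in wild type and 31.2 ± 5.5 in the overexpressor) and WHY1 (0.98 ± 0.15) rose, WHY3 with an overlapping gene in the annotation. MSH1, a MutS homologue of plastids and mitochondria, was at 0.71 ± 0.19 and did not pass in edgeR, while DESeq2's adjusted p was 0.0440. Plastid-encoded (133) and mitochondrion-encoded (152) gene rows held 0 counts in every library and gave no value.

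The flower, root and stem markers describe the makeup of the harvested plants. Floral organ markers were higher in 9 of 9 tested members with a median of 1.1 (camera adjusted p = 0.0248, and adjusted p = 0.652 with an estimated correlation). In edgeR 0 of them passed, 1 had an unadjusted p under 0.05 and DESeq2 called 0. Their summed level was low, at 18.8 and 9.88 CPM in wild-type plants and 29.3 and 23.9 CPM in overexpressor plants. Of these, CAL was at 0.180 ± 0.051 and 0.568 ± 0.185 CPM. Tapetum and pollen markers had a median of 1.56 over 9 members (camera adjusted p = 0.0206, and adjusted p = 0.531 with an estimated correlation), and 4 rose. LAP5 had the smallest p of the list (2.12 ± 0.35), but it overlaps 2 annotated genes and is uncertain. The tapetum and pollen sums were 16.3 and 17.1 CPM in wild type and 37.9 and 20.6 CPM in the overexpressor. Both calls were lost without overexpressor plant 1 (camera adjusted p = 0.0737 for the floral list and 0.0861 for tapetum and pollen). The floral call was also lost without wild-type plant 2 (0.162), and the tapetum and pollen call without wild-type plant 1 (0.0618). Secondary wall and stem markers did not pass (15 members, median -0.64, camera adjusted p = 0.381), with 0 members past in edgeR, 4 at an unadjusted p under 0.05 and 2 called by DESeq2, and their sums were 229 and 419 CPM in wild type against 237 and 271 CPM. In that list XCP1, a xylem protease that overlaps another gene, was at 24.0 ± 1.0 CPM and 38.7 ± 3.9 CPM. Without wild-type plant 1 the list passed as lower (camera adjusted p = 3.42e-04). Of the root markers 3 were tested, with 0 past in edgeR, 0 at an unadjusted p under 0.05 and 0 called by DESeq2 (RCI3, -0.39 ± 0.25), with sums of 46.8, 47.3, 48.7 and 33.9 CPM in the order of the depths above.

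The other lists here did not pass as sets, and most of them had members that rose or fell. Flowering-time genes were lower in 15 of 24 members (median -0.26, camera adjusted p = 0.0955), and TEM1, a repressor of flowering, fell from 166 ± 2 CPM to 55.2 ± 16.1 (3.01-fold). That list passed as lower without overexpressor plant 2 (camera adjusted p = 0.0162). Antioxidant genes went both ways (8 higher and 8 lower), with a median of -0.03, a mean of 0.13 and a set test pointing up (camera adjusted p = 0.587). The 4 that rose were the iron superoxide dismutases FSD1 (90.8 ± 17.5 and 320 ± 50 CPM, 3.52-fold higher), FSD2 (0.86 ± 0.12) and FSD3 (1.28 ± 0.22), and SAPX, an ascorbate peroxidase (1.28 ± 0.21). Iron homeostasis genes included 2 that rose, the ferritins FER3 (0.71 ± 0.16) and FER4 (0.75 ± 0.16), and 2 that fell, BHLH101 (-2.58 ± 0.12) and FER1 (-1.0 ± 0.23), with camera adjusted p = 0.789. In the phosphate starvation list (camera adjusted p = 0.327), SRG3 (17.5 ± 2.9 and 4.32 ± 1.56 CPM, with an overlapping gene) and PAP17 (-1.47 ± 0.24) fell. The mitochondrial dysfunction list (camera adjusted p = 0.327) included NDA2, an alternative NAD(P)H dehydrogenase (24.2 ± 1.3 and 13.5 ± 1.9 CPM), and the alternative oxidase AOX1D (-3.62 ± 0.66), and both fell. Cytokinin response genes did not pass (10 members, median 0.58, camera adjusted p = 0.0997). In edgeR 0 passed, 5 had an unadjusted p under 0.05 and DESeq2 called 2, and CRF2 had the smallest p of them (0.94 ± 0.24, edgeR adjusted p = 0.0878). The cytokinin list passed as higher without wild-type plant 2 (camera adjusted p = 0.0293) or overexpressor plant 1 (0.0049).

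Jasmonate and touch response genes differed more between the overexpressor plants than between genotypes. Jasmonate response genes had positive fold changes in 21 of 22 members (median 1.04, camera adjusted p = 0.115), yet the median log2 difference of overexpressor plant 1 over plant 2 was 2.54, and that of wild-type plant 1 over plant 2 was -0.74. The list passed as higher without overexpressor plant 2 (camera adjusted p = 2.36e-07) or wild-type plant 2 (0.0389). JAZ7, a jasmonate-induced repressor, was at 6.49 and 17.7 CPM in wild-type plants and at 81.7 and 0.613 CPM in overexpressor plants 1 and 2. JMT, which methylates jasmonate, rose (2.29 ± 0.39). The defensin PDF1.2 fell (-4.24 ± 0.73), with a count made uncertain by near-identical copies. Touch and rapid wound response genes had a median of 0.01, a mean of -0.05 and a set test pointing down (15 members, camera adjusted p = 0.327). The median log2 difference in that list was 1.87 for overexpressor plant 1 over plant 2 and -0.84 for the wild-type plants. In edgeR 0 touch genes passed over the list alone, 1 had an unadjusted p under 0.05 and DESeq2 called 1, and ERF104 had the smallest p (-1.09 ± 0.23, edgeR adjusted p = 0.0720). That list was lower without overexpressor plant 1 (camera adjusted p = 2.32e-05) and higher without overexpressor plant 2 (0.0470). Over all tested genes, 1466 differed by over 2-fold between the overexpressor plants and 914 between the wild-type plants.

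**Figure D3:**
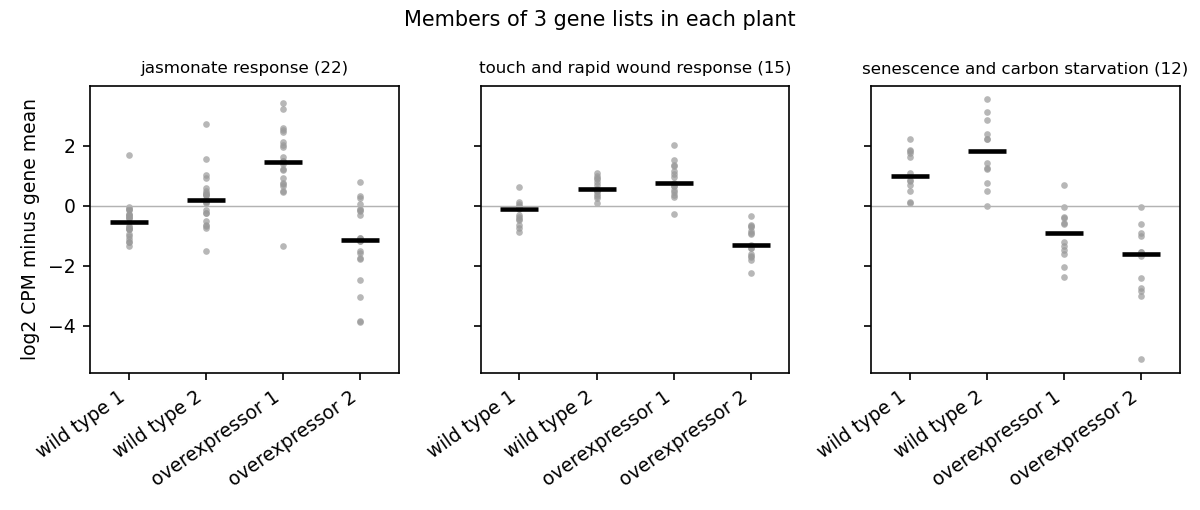
Log2 CPM of each member minus that gene's mean over the 4 plants (y axis), by plant (x axis), for the jasmonate, touch and senescence lists, with 1 grey point per gene and a black bar at the median. In the jasmonate list the medians are 1.47 and -1.13 in overexpressor plants 1 and 2, while in the senescence list both overexpressor plants (-0.91 and -1.61) lie below both wild-type plants (0.98 and 1.82).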

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

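The tests of library depth and of a mislabelled plant in this part were chosen after the plant-to-plant difference had been seen.

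Reads whose alignment was not unique, a row outside the gene counts, made up 5.16% and 5.61% of counted reads in overexpressor plants 1 and 2, above the 4.60% and 4.18% in wild-type plants 1 and 2. The Wilson 95% intervals, which cover counting error only, were 5.16% to 5.17%, 5.61% to 5.62%, 4.59% to 4.61% and 4.17% to 4.18% in that order.

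Jasmonate and touch genes differed between the 2 overexpressor plants, with a median log2 difference of 2.27 over the 37 tested members of both lists, plant 1 over plant 2. Of 10000 random lists matched on expression, the middle 95% gave -0.13 to 0.04. The values were already scaled for depth, and these 2 lists were picked after their difference was seen. The comparison could thus hardly have come out otherwise and does not decide on library depth. A mislabelled plant is argued against by PPD3 itself, at 27.6 times the higher wild-type plant in the lower overexpressor plant. Outside the lists the overexpressor plants correlated across genes at 0.968 and at most 0.958 with a wild-type plant, but a shared genotype alone would give that order, so the bound set in advance was too weak, and the wild-type plants correlated at 0.982 (genes are not independent replicates). A general change in RNA quality in 1 plant thus cannot be told apart from other differences between the plants, and no biological explanation was tested, since both plants are of 1 group.

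Flower, dividing-cell and senescence lists parted between the genotypes. Library scaling is argued against, since the 3 list medians moved by at most 0.0426 on the log2 scale under 3 other scalings. More flower tissue in the overexpressor harvest cannot be told apart from an effect of genotype: 66.7% of floral organ, tapetum and pollen markers (12 of 18) were higher in both overexpressor plants, between the share set in advance for more flower tissue and the share set against it. An effect of PPD3 level on stage or on these genes stays open and was not tested apart from tissue makeup.

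Circadian clock genes were lower in 21 of 22 tested members. Harvest at different times of day predicts that morning and evening genes part, and the difference of their medians (8 morning and 11 evening genes) was -0.14 on the log2 scale, with a bootstrap 95% interval of -0.92 to 0.08 and a permutation p of 0.178 over genes. Because that interval reaches beyond the bound set in advance, harvest time cannot be told apart from an effect of genotype, which stays untested.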

How the results depend on the processing

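Alternatives added after the data were seen are the crossed block, limma with voom, robust moderation, the 523 genes left out, the symbol rule for 3 loci, PPD3 left out of its list, and DESeq2 with plants left out or with blocks. Where a count or call moved below, the cause was not tested unless the setting tests fewer genes or plants. The 3 other scalings, robust moderation, a 2-fold minimum and leaving out organelle genes (all at 0 counts, so nothing could move) each kept 1 call, NIT2. DESeq2 called 3672 genes (1703 higher, 1969 lower), edgeR without a filter 13 (3 higher, 10 lower), and an adjusted p of 0.10 gave 4129 (1904 higher, 2225 lower). The filter of 5 CPM gave 0 calls and limma with voom 0, where 5452 and 6573 genes had an unadjusted p under 0.05. Leaving out the jasmonate and touch members and genes over 4-fold apart between plants of 1 genotype gave 1773 calls (740 higher, 1033 lower), a selection that favours calls because it removes spread. Without each plant in turn, edgeR gave 0 to 0 calls, with 3200 to 6174 genes at an unadjusted p under 0.05, the lone plant being assumed to vary like the others. NIT2's log2 fold change then ran from -4.32 to -4.18 and its edgeR adjusted p from 0.0776 to 0.299. DESeq2 gave 4505 calls without wild-type plant 1 (2352 higher, 2153 lower) and 510 without wild-type plant 2 (156 higher, 354 lower). It gave 1740 without overexpressor plant 1 (465 higher, 1275 lower) and 962 without overexpressor plant 2 (299 higher, 663 lower). All 3672 of its calls with every plant kept their sign each time. Those genes were selected from the same plants, so their signs could hardly have changed, and this does not test stability.

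The log2 fold change of PPD3 was 5.13 with DESeq2, 5.11 without a filter, 5.16 with the crossed block and 5.13 without the unlike genes, past 0.05 in each, and ran from 4.87 to 5.40 without each plant. Over 539 values of PPD3 and the other named genes under alternatives, 453 kept their side of the threshold, 79 became calls, 7 (NIT2) lost theirs and none reversed.

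Deviations of same-numbered plants correlated at -0.28 across genes. Each genotype gives only its own difference between plants, and genes are not independent. The correlation thus cannot decide whether the replicate numbers pair the plants. With the replicate number as a block, edgeR called 0 genes (4806 at an unadjusted p under 0.05) and DESeq2 1264 (394 higher, 870 lower), and 3 more lists passed, the photosystem (camera adjusted p = 0.0457), jasmonate (0.0457) and cytokinin (0.0339) lists. With the crossed block, edgeR called 137 (17 higher, 120 lower) and DESeq2 2506 (1048 higher, 1458 lower), and the photosystem (camera adjusted p = 0.0253) and jasmonate (0.0310) lists passed.

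Of the 26 lists, 16 passed camera, and 13 to 19 over the other gene-level settings and the symbol rule. With the 5 CPM filter 24 lists were tested and 13 passed, the floral and the tapetum and pollen lists having too few members left, and without the 523 genes 24 were tested, the jasmonate and touch lists being left out. With PPD3 left out of its list 14 passed, and the PsbP (camera adjusted p = 0.0534) and heat shock (0.0517) lists did not. With an estimated correlation, a run on 2 residual degrees of freedom with little power, 0 passed, and with fry 0. Of the 4 tested tissue marker lists 3 passed, 1 of the 2 still tested with the 5 CPM filter, 0 with an estimated correlation and 0 with fry, and 1 to 3 without each plant. The touch list turned to higher without overexpressor plant 2 (camera adjusted p = 0.0470), and its adjusted p without each plant ran from 2.32e-05 to 0.925. Lists that passed in all 14 of the settings that kept the lists as written and camera's preset correlation were the PsbP, Calvin cycle, organelle maintenance, clock, cold and ABA, salicylic acid, flavonoid, glucosinolate, auxin, senescence, DNA methylation and dividing-cell lists. Robust moderation and leaving out organelle genes were among those settings and could not move camera. It used the voom values, and the organelle rows held 0 counts. Depth limits genes near the filter, such as the floral markers, more than the other genes named.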

Other observations

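The gene families in this part were chosen after the data were seen, by words in the annotated product, and tested with camera over 18 families. The run with an estimated correlation again had 2 residual degrees of freedom and little power, so a call lost there decides little. A family therefore takes in some related proteins whose product carries the word. No family median changed sign under 3 other scalings.

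Ribosomal proteins had positive fold changes in 281 of 310 tested genes, with a median log2 fold change of 0.46 (camera adjusted p = 9.94e-17, and adjusted p = 0.455 with an estimated correlation), and DESeq2 called 114 higher and 6 lower. Pentatricopeptide repeat proteins, which process organelle RNA, were higher in 210 of 237 (median 0.33, camera adjusted p = 1.13e-08, and adjusted p = 0.455 with an estimated correlation). Kinesins, motors of the spindle and cell plate, were higher in 39 of 42 (median 0.62, camera adjusted p = 1.25e-09, and adjusted p = 0.455 with an estimated correlation). Proteins of DNA replication were higher in 23 of 24, with PCNA1 at 11.5 CPM in wild type and 24.5 in the overexpressor and MCM2 at 23.7 and 41.6 CPM (camera adjusted p = 1.48e-05, and adjusted p = 0.455 with an estimated correlation). Products that name a histone were higher in 34 of 47 (median 0.51, camera adjusted p = 1.79e-04, and adjusted p = 0.455 with an estimated correlation). Without 5 methyltransferases and deubiquitinases that act on histones, 34 of 42 were higher (median 0.65, camera adjusted p = 4.55e-07, and adjusted p = 0.455 with an estimated correlation), while the drought-induced linker histone HIS1-3 went the other way, at 47.9 CPM in wild type and 3.62 in the overexpressor (DESeq2 adjusted p = 5.46e-35). The dividing-cell markers, higher in the same plants, stand beside the kinesin, replication and histone values, with sums of 134 and 110 CPM in wild-type plants and 220 and 211 CPM in overexpressor plants. Many histone genes have near-identical copies, so single values are uncertain.

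Autophagy proteins were lower in 17 of 17 tested genes (median -0.43, camera adjusted p = 1.13e-04, and adjusted p = 0.455 with an estimated correlation), ATG8E among them at 59.4 and 22.6 CPM in wild type and overexpressor. SAUR-like auxin-response proteins were lower in 41 of 54 (median -0.79, camera adjusted p = 1.87e-04), WRKY factors in 42 of 56 (median -0.40, camera adjusted p = 0.0010), NAC factors in 43 of 63 (median -0.23, camera adjusted p = 0.0025), TIR-NBS-LRR immune receptors in 58 of 71 (median -0.30, camera adjusted p = 6.48e-05), cytochrome P450s in 89 of 143 (median -0.29, camera adjusted p = 0.0125) and galactinol and raffinose synthases in 4 of 5 (median -0.88, camera adjusted p = 0.0448). None of these 6 calls held in the low-power run with an estimated correlation (camera adjusted p = 0.455 to 0.481). The TIR-NBS-LRR call was lost without overexpressor plant 2 (camera adjusted p = 0.153) and the cytochrome P450 call without overexpressor plant 2 (0.0513) or wild-type plant 1 (0.0555). The galactinol and raffinose synthase call was lost without overexpressor plant 1 (0.0809) or wild-type plant 2 (0.0988). Expansins, protein phosphatases 2C, UDP-glycosyltransferases, peroxidases, tubulins and aquaporins did not pass (camera adjusted p from 0.145 to 0.301), though expansins passed as higher without wild-type plant 2 (0.0266).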
